A study of Rattus norvegicus with 4 samples.

How the data were processed

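Poly(A) RNA of RSC96 rat Schwann cells of generation 4 was made into libraries with an Ultra RNA kit and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The authors deposited FPKM (fragments scaled by transcript length and by the mapped fragments of the library) in a table of genes and a table of lncRNAs, each with 1 column per library, so replicates were not pooled. Per the submitters' processing notes, the genome build was rn5 and the tools TopHat2 and Cuffdiff, with no versions, roles or order. The annotation, any filters and any scaling between libraries are not given in the sources used here. Strand was not stated, so overlapping and antisense genes cannot be told apart, and reads shared between near-identical copies may have been split or assigned to either copy.

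FPKM are not counts, so no count test was used. Low rows step by the worth of 1 read, and the commonest ratio of rows under 0.15 FPKM between libraries gave relative depths of 1.00 and 1.28 for control libraries 1 and 2, and 1.08 for both IL-22 libraries. The deposited FPKM summed to 636818 and 630119 in the controls and 658909 and 669549 with IL-22 in the gene table, and to 314730, 257644, 330844 and 299090 in the lncRNA table. Absolute depth is unknown, so no counting intervals are given. An exact 0 in such a table can be a failed estimate. Of 132 ribosomal protein and oxidative phosphorylation genes 0 were listed at 0 in any library, and genes at 0 are still described only as listed at 0, with each library's value. The 10 highest rows held from 7.87% to 8.99% of the summed FPKM of the gene table.

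Of 17778 gene rows 12482 were above 0 in at least 1 library and 5296 were at 0 in all 4. Symbols are those of the table, where 540 rows carry a number suffix for a further copy. Of the 17778 rows 14976 matched a symbol in a RefSeq gene table of the assembly GRCr8, and 17307 a symbol or a synonym. That table was used only for names, since its build differs from rn5, and no coordinates are given. Gene rows with a mean of at least 1 FPKM over the 4 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05, no covariates). lncRNA rows with a mean of at least 0.5 FPKM were tested on log2(FPKM + 0.5) in a fit of their own. A difference on these scales understates the change of low genes. Folds are ratios of mean FPKM. With 2 libraries against 2, an exact permutation test of a gene cannot go below 0.333, so p-values rest on the spread that limma shares across genes. A gene was called separated when its groups did not overlap and differed by at least 1 on the log2 scale.

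The samples, main tests, naming rule and 36 gene lists (1245 genes, of which 1164 had a row, 6 through a synonym or letter case) were fixed before the data were examined, as were the alternatives other than those said to be chosen later. The lists were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 32 lists with at least 5 tested members, and lists with fewer got values only. Where rows share a symbol, the row with the highest mean stands for it. The genes named were the 10 largest differences per direction among those past the limma threshold, up to 4 members past it per list by absolute difference or the 2 highest where none passed, and Stat3, Socs3, Il22ra1, Il10rb, Mki67, Pcna, Ccnd1, Cdkn1a, Sox10, S100b, Ngfr and Jun. Some genes that the rule takes are not reported here. Genes outside this rule are said to have been named after their values were seen, or stand in the list counts they complete. The rule took 3 lncRNAs per direction, of which 2 are printed, since their identifiers are not matched to names.

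Alternatives were other pseudocounts and filters, quantile normalization, median-of-ratios size factors, limma without trend or with robust eBayes, the replicate number as a block, leaving out each library, and, for lists, an estimated correlation, camera on ranks and fry. Where a library was left out, its partner was assumed to vary like the other group. The fits were tested on simulated continuous values with the control means and the smoothed spread of the real tables. For the gene table (9485 rows) limma recovered 92% of 50 genes changed 1.5-fold and 100% of those changed 2-, 4- and 8-fold, with 9 false calls. For the lncRNA table (4454 rows) it recovered 2%, 6%, 70% and 84% of 50 lncRNAs changed 1.5-, 2-, 4- and 8-fold, with 3 false calls. These values had no whole-read steps and no rows listed at 0, unlike the real lncRNA rows, so the rates and false calls may not carry over. Camera called 1 of 1 changed and 0 of 20 unchanged simulated lists. The simulated genes varied independently and the changed list held only raised genes, so this does not test camera on lists of correlated genes. Depth ratios and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.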

Results

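RNA was sequenced from RSC96 cells, an established line of rat Schwann cells, the glia that ensheath the axons of peripheral nerves. After a night without serum, cells received 100 ng/ml of recombinant rat IL-22, a cytokine of the IL-10 family that signals through STAT3, for 48 h, or its solvent, 0.1% bovine serum albumin, for a time that the labels do not state. The title of the series concerns Schwann cell proliferation and nerve regeneration under IL-22. Each group had 2 libraries, and nothing in the labels says that these came from separate cultures. The limma p-values therefore measure only the spread between these libraries, which may be technical. Expression was given as FPKM for 17778 gene rows and 37866 lncRNA rows. Read totals were not given, but the spacing of low values put the depth, relative to control library 1, at 1.28 for control library 2 and at 1.08 for both IL-22 libraries. Gene rows above 0 numbered 11196 and 11412 in the control libraries and 11641 and 11617 in the IL-22 libraries. Across tested genes, which are not independent replicates, log2 values of the 2 libraries of a group correlated with a Pearson r of 0.995 in the controls and 0.996 with IL-22. The summed FPKM of the ribosomal RNA rows were 7055 and 4918 in the controls and 3594 and 3606 with IL-22. These sums come largely from different rows and do not measure a change in ribosomal RNA content. In controls Rn28s (4015 and 2715 FPKM) and Rn45s (2872 and 2103 FPKM) dominated, and both were listed at 0 with IL-22. The row Rn5-8s was at 27.6 and 16.5 FPKM in controls and at 593 and 614 FPKM with IL-22. Values are mean FPKM ± SD of the 2 libraries of a group, and differences are IL-22 minus control on the log2(FPKM + 1) scale with the standard error from limma.

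After IL-22, genes of DNA replication and mitosis fell, while cytokine genes, STAT3 target genes and genes of the amino-acid response, glycolysis and cholesterol synthesis rose by camera with a preset correlation. With an estimated correlation none of these lists passed (adjusted p from 0.232 to 0.252). That version of camera rests on the 2 residual degrees of freedom of this design, which leaves it little power. The preset version takes its degrees of freedom from the number of genes, so its p-values do not measure replication across libraries. The estimated correlations were 0.213 for G1/S and 0.283 for glycolysis genes, but -0.0025 for G2/M and 0.0050 for cytokine genes. Those of G1/S and glycolysis genes lie above the preset 0.01, so the preset p-values of these lists may be far too small. Those of G2/M and cytokine genes lie below it and these lists failed alike, so a failure does not show that correlation undid a list. The chemokine gene Cxcl1, which attracts neutrophils, rose 96.7-fold from 4.14 ± 0.580 to 400.3 ± 19.2 FPKM, and Csf3, which encodes the granulocyte growth factor G-CSF, rose 69.6-fold from 1.48 ± 0.0796 to 103 ± 0.729 FPKM. Socs3, the feedback inhibitor that STAT3 induces, rose from 164 ± 3.21 to 515 ± 24.8 FPKM, and the replicative helicase gene Mcm7 fell from 201 ± 7.68 to 44.8 ± 0.680 FPKM. Of 9485 gene rows tested with limma, 2619 were higher and 2918 lower with IL-22, and 3948 did not pass the threshold. The differences were mostly small: 444 genes were higher and 269 lower by at least 1 log2 with no overlap between the groups. Groups did not overlap in 80.1% of tested genes, where chance gives 33.3%. The median difference over all tested genes was -0.022. By camera, 16 of 32 tested gene lists passed, 13 higher and 3 lower, and 0 of them passed with an estimated correlation, where the smallest adjusted p was 0.232. Counts of list members adjusted over the list alone are given where they differ from those over all genes, and were otherwise equal.

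**Figure D1:**
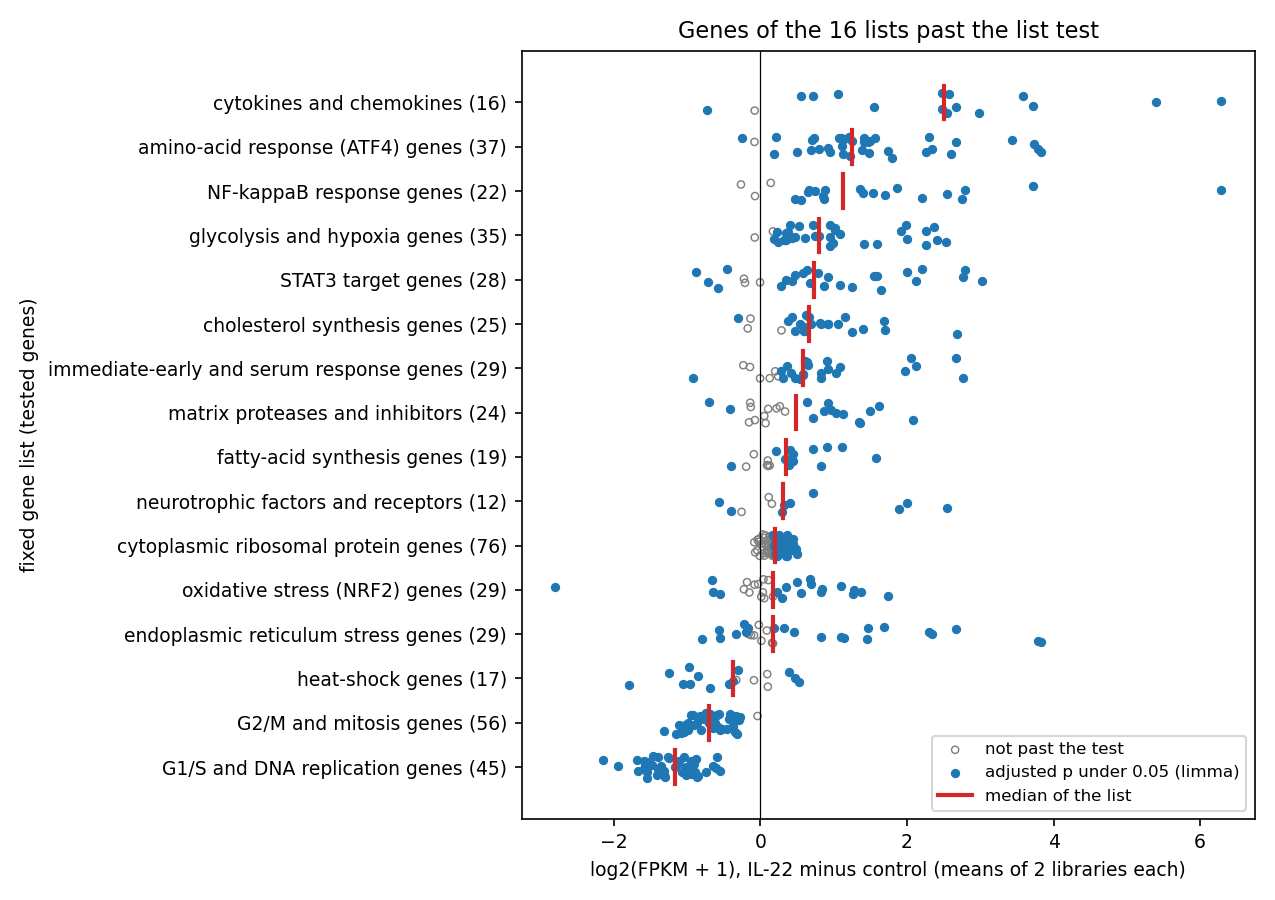
Log2(FPKM + 1) differences between IL-22 and control (x axis, means of 2 libraries each) for the tested genes of the 16 fixed lists past the camera test (y axis, number of tested genes in brackets). Each point is a gene, filled where its limma adjusted p was under 0.05, and red bars mark list medians, from 2.51 for cytokines and chemokines to -1.17 for G1/S and DNA replication genes.

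Cell-cycle genes fell across both phases listed. All 45 tested members of the G1/S and DNA replication list were lower, with a median difference of -1.17 (camera adjusted p = 1.73e-19, adjusted p = 0.248 with an estimated correlation). Besides Mcm7 (-2.14 ± 0.06, limma adjusted p = 6.9e-08), the largest differences were those of Cdc6, which loads the helicase (-1.95), the checkpoint adaptor Clspn (-1.69) and the helicase subunit Mcm5 (-1.67). Pcna, the sliding clamp of DNA polymerase, fell from 134 ± 11.6 to 59.1 ± 5.99 FPKM (-1.17 ± 0.09, limma adjusted p = 8.88e-06). In the G2/M and mitosis list 55 of 56 tested members were lower, with a median of -0.70 (camera adjusted p = 4.09e-16, adjusted p = 0.232 with an estimated correlation). The remaining member, Cenpf, measured 8.40 and 8.16 FPKM and did not pass. Cyclin A2 (Ccna2, -1.31), the transcription factor Mybl2 (-1.15), Gtse1 (-1.10) and the kinetochore gene Ndc80 (-1.09) led the list. Mki67, the gene of the proliferation marker Ki-67, fell from 152 ± 14.9 to 82.7 ± 3.13 FPKM (-0.87 ± 0.08, limma adjusted p = 2.47e-05). Cyclin D1 (Ccnd1) fell from 614 ± 1.60 to 411 ± 3.08 FPKM (-0.58 ± 0.06, limma adjusted p = 4.64e-05).

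Inhibitors of the cell cycle and related stress-response genes moved both ways, with 15 higher and 10 lower of 30 tested (median 0.09, camera adjusted p = 0.324). Gdf15, a stress-induced cytokine, rose from 9.41 ± 0.617 to 137 ± 5.60 FPKM, and Gadd45a (1.75), the proapoptotic Pmaip1 (1.75) and Sesn2 (1.47) also rose. Among the lower members, picked after their values were seen, were Cdkn2c (-1.13) and Ccng1 (-1.20). Cdkn1a, the gene of the cyclin-dependent kinase inhibitor p21, measured 196 ± 13.5 and 227 ± 4.34 FPKM (0.22 ± 0.07, limma adjusted p = 0.0213), a call that was lost under 5 of 15 alternatives: without the filter, without the trend, and without control library 2, IL-22 library 1 or IL-22 library 2 (limma adjusted p from 0.00656 to 0.134 over all 15). Cyclins D and mitogenic signalling genes gave 10 higher and 8 lower of 32 (median 0.02, camera adjusted p = 0.454), with the phosphatases Dusp5 (1.91) and Dusp6 (0.78) and the EGF receptor ligands Hbegf (1.49) and Areg (0.94) higher. Apoptosis regulators gave 11 higher and 9 lower of 32 (camera adjusted p = 0.653). Their median was -0.06, while their mean of 0.17 and the test pointed up, and Casp4 (3.06), Birc3 (1.87) and Bbc3 (1.23) were the largest differences beside Pmaip1. Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, gave 5 higher and 1 lower of 16, or 3 and 0 adjusted over the list alone (median 0.29, camera adjusted p = 0.148). Of these, Hist1h1d rose by limma (0.76), while Hist1h2bh (0.91) lost its call without control library 1. Hist1h1a (0.56) and Hist2h4 (-0.89) each lost their call under 6 of 14 alternatives. Both lost it with a pseudocount of 0.1, without the filter, without the trend, and without control library 2 or IL-22 library 1, Hist1h1a also with quantile normalization and Hist2h4 also without control library 1.

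Il22ra1, which encodes the IL-22-binding chain, was listed at 0 in all 4 libraries, and Il10rb, which encodes the shared chain, measured 7.96 ± 0.609 FPKM in controls and 8.83 ± 0.497 with IL-22 (limma adjusted p = 0.301). Among IL-22 receptor and JAK-STAT components 6 were higher and 4 lower of 13 (median 0.13, camera adjusted p = 0.324). Stat3 rose from 46.1 ± 1.07 to 73.8 ± 0.0422 FPKM (0.67 ± 0.07, limma adjusted p = 3.95e-05), Jak2 rose (0.61), and Pias3, an inhibitor of STAT3, fell (-0.54). The oncostatin M receptor gene Osmr was higher by 0.51, a call lost with quantile normalization and without IL-22 library 1 (limma adjusted p from 0.0026 to 0.083 over 14 alternatives). Of 28 tested STAT3 target genes 21 were higher and 4 lower (median 0.74, camera adjusted p = 1.69e-06, adjusted p = 0.24 with an estimated correlation). Socs3 rose by 1.65 ± 0.06 (limma adjusted p = 1.99e-07), the transcription factor Cebpd from 12.5 ± 2.03 to 108 ± 0.188 FPKM (3.02), the NF-kappaB cofactor Bcl3 by 2.79, Ier3 by 2.76 and the adhesion molecule Icam1 by 2.21. The 4 lower members, named after their values were seen, were Socs1 (-0.88), Irf1 (-0.71), Birc5 (-0.46) and Ccnd1. Acute-phase and antimicrobial genes had 2 members above the expression minimum, of which the copper carrier ceruloplasmin (Cp) rose from 1.01 ± 0.306 to 2.91 ± 0.491 FPKM (limma adjusted p = 0.00142), while Hp measured 1.39 and 1.11 FPKM and did not pass.

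**Figure D2:**
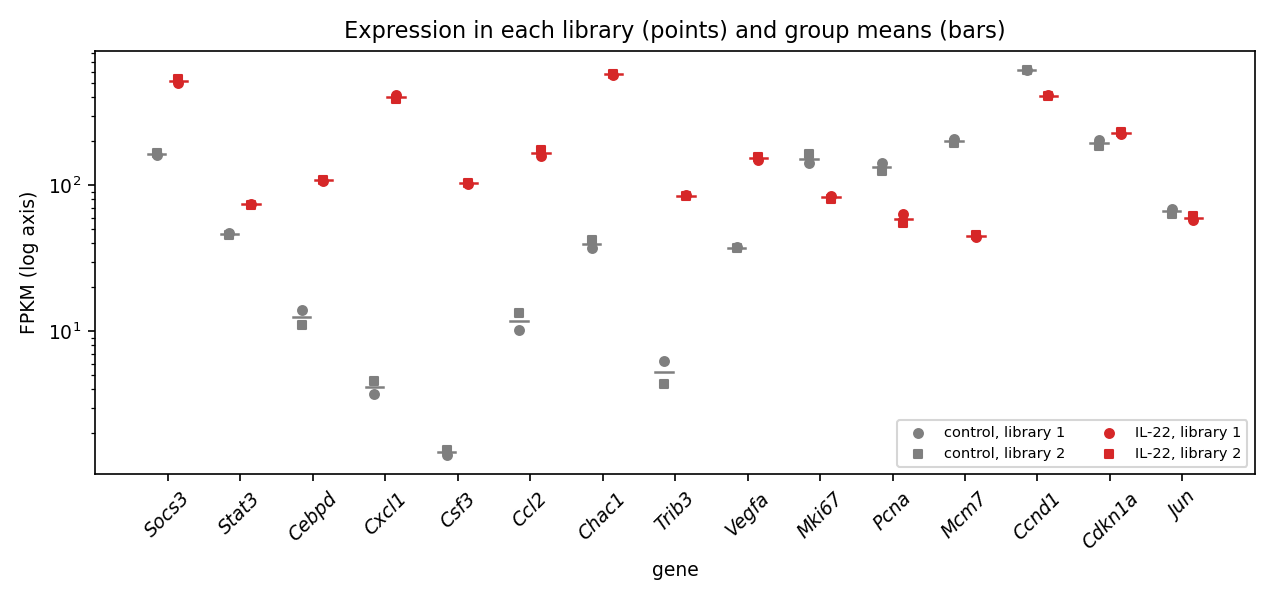
FPKM in each library (points, log axis) and group means (bars) for 15 genes, with controls in grey and IL-22 in red. Chac1 and Trib3 (amino-acid response) and Cxcl1, Csf3 and Ccl2 (cytokines) lie higher with IL-22, Mki67, Pcna, Mcm7 and Ccnd1 lower, and Jun measured 66.2 and 60.0 FPKM.

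Of 16 tested cytokine and chemokine genes 14 were higher and 1 lower (median 2.51, camera adjusted p = 3.49e-08, adjusted p = 0.232 with an estimated correlation). The size of that median rests on the settings, at 0.72 without the filter and 1.26 with a pseudocount of 5. Beside Cxcl1 (6.29 ± 0.09, limma adjusted p = 3.8e-10) and Csf3 (5.39 ± 0.09, limma adjusted p = 6.52e-10), the monocyte attractant Ccl2 rose from 11.7 ± 2.22 to 166 ± 9.63 FPKM and Cxcl3 from 1.34 ± 0.542 to 26.9 ± 2.41 FPKM. Il10, named after its values were seen, was listed at 0 in both controls and at 6.09 and 7.88 FPKM with IL-22. The lower member was Csf1, a macrophage growth factor (-0.73), and Cxcl12 measured 118 and 112 FPKM and did not pass. NF-kappaB response genes gave 19 higher and 0 lower of 22, or 19 and 1 adjusted over the list alone (median 1.12, or 0.73 with a pseudocount of 5, camera adjusted p = 4e-10, adjusted p = 0.232 with an estimated correlation). Cxcl1, Ccl2 and Bcl3 are in this list too, and the nitric oxide synthase gene Nos2 was at 0 and 0.0252 FPKM in controls and at 5.69 and 5.91 FPKM with IL-22. Of 20 macrophage and leukocyte marker genes 18 lay under 1 FPKM in both group means. The other 2 did not pass the limma test, Cd14 at 2.19 ± 0.0405 and 3.54 ± 1.51 FPKM (adjusted p = 0.0833) and Cd68 at 1.39 ± 0.243 and 0.886 ± 0.157 FPKM (adjusted p = 0.126). The difference of Cd14 rested on IL-22 library 1, at 4.61 against 2.47 FPKM in IL-22 library 2.

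Interferon-stimulated genes split, with 8 higher and 17 lower of 31, or 9 and 17 adjusted over the list alone (median -0.30, camera adjusted p = 0.324). The antiviral genes Rsad2 (2.24), Oasl (1.51) and Dhx58 (1.23) and the chemokine gene Cxcl10 (1.07) rose. Members that fell, picked after their values were seen, included Isg15 (-0.93), Irf7 (-0.92), Ifi44 (-1.06) and the immunoproteasome subunit Psmb8 (-0.99). Psmb10, another immunoproteasome subunit, was among the 10 largest falls of all genes, from 85.2 ± 4.12 to 10.8 ± 0.189 FPKM (-2.87 ± 0.08, limma adjusted p = 2.87e-08). Immediate-early and serum response genes gave 22 higher and 1 lower of 29, or 23 and 1 adjusted over the list alone (median 0.58, or 0.34 with a pseudocount of 5, camera adjusted p = 8.78e-07, adjusted p = 0.248 with an estimated correlation). Atf3 (2.66), Junb (2.12) and Egr2 (2.06) rose with Ier3. Jun measured 66.2 ± 3.73 and 60.0 ± 2.62 FPKM and did not pass (limma adjusted p = 0.127).

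Genes induced by ATF4 in the amino-acid response rose nearly throughout, with 35 higher and 1 lower of 37 tested and a median of 1.25 (camera adjusted p = 1.18e-17, adjusted p = 0.232 with an estimated correlation). Chac1, which degrades glutathione, rose from 39.6 ± 3.80 to 577 ± 5.82 FPKM (3.83 ± 0.07, limma adjusted p = 3.55e-09), the pseudokinase gene Trib3 from 5.29 ± 1.30 to 84.7 ± 0.692 FPKM (3.78) and Nupr1 from 0.609 ± 0.107 to 16.4 ± 0.729 FPKM (3.44). Endoplasmic reticulum stress genes gave 14 higher and 7 lower of 29, or 14 and 8 adjusted over the list alone (median 0.17, camera adjusted p = 0.00603, adjusted p = 0.248 with an estimated correlation). The largest differences there were those of Chac1, Trib3, Atf3 and the asparagine synthetase gene Asns (2.34), which are also ATF4 targets. The 6 members that the amino-acid response list shares were all higher, with a median of 2.50, and the other 23 gave 8 higher and 7 lower with a median of 0.016. Glycolysis and hypoxia genes gave 33 higher and 0 lower of 35 (median 0.81, camera adjusted p = 6.26e-14, adjusted p = 0.252 with an estimated correlation). The hypoxia-induced Ndrg1 (2.53), the aldolase gene Aldoc (2.41), Ankrd37 (2.37) and the oxidoreductase gene Ero1l (2.26) led them. Vegfa, the vascular growth factor gene, rose from 37.5 ± 0.0776 to 153 ± 5.19 FPKM.

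Lipid synthesis genes rose. Of 25 cholesterol synthesis genes 21 were higher and 1 lower (median 0.66, camera adjusted p = 4.14e-08, adjusted p = 0.232 with an estimated correlation). Insig1, a sterol sensor, rose from 19.4 ± 0.893 to 130 ± 1.65 FPKM (2.68 ± 0.07, limma adjusted p = 2.75e-08), and Fdps (1.70) and Msmo1 (1.39) also rose. Of 19 fatty-acid synthesis genes 12 were higher and 1 lower (median 0.35, camera adjusted p = 0.00152, adjusted p = 0.248 with an estimated correlation), with the acyltransferase gene Dgat2 (1.58), Acss2 (1.12), the desaturase gene Scd (0.91) and the regulator Srebf1 (0.83) in front.

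Schwann cell genes were mostly low in these cells and moved both ways. Sox10, S100b and Ngfr, which mark the Schwann lineage or immature and injured Schwann cells, were at or below 0.119 FPKM in every library and were not tested. Of 11 tested lineage genes 4 were higher and 3 lower (median 0.05, camera adjusted p = 0.516). The adhesion molecule Cadm4 (1.86) and Desert hedgehog (Dhh, 1.11) rose and Gfap fell (-0.70), and Erbb3, a neuregulin receptor gene, was higher by 0.55, a call lost with quantile normalization and without IL-22 library 1 or IL-22 library 2 (limma adjusted p from 0.00256 to 0.197 over 14 alternatives). Of 29 myelin genes with a row 12 were tested, of which 7 were higher and 2 lower (median 0.23, or 0.027 without the filter, camera adjusted p = 0.0901). Cadm4 and Dhh are in this list too. Egr2, the master regulator of myelination, rose from 0.460 ± 0.0283 to 5.11 ± 0.686 FPKM and Pmp22, a myelin membrane protein gene, from 19.2 ± 1.40 to 41.6 ± 0.903 FPKM. Genes of the injury-induced repair state gave 7 higher and 9 lower of 22 (median -0.04, mean 0.14, camera adjusted p = 0.866 with the test pointing up). There Atf3, Lif (2.54) and Egr1 (1.98) rose and Id2, which restrains differentiation, fell from 47.3 ± 1.96 to 7.36 ± 1.44 FPKM (-2.54 ± 0.12, limma adjusted p = 5.26e-07).

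Neurotrophic factors and receptors gave 7 higher and 2 lower of 12 (median 0.31, or 0.022 without the filter, camera adjusted p = 0.0409, adjusted p = 0.379 with an estimated correlation). That call was also lost without the filter, with quantile normalization, on ranks, and without control library 1, control library 2 or IL-22 library 2 (camera adjusted p from 0.0127 to 0.431 over 13 alternatives). Lif, Vegfa, the glial growth factor gene Gdnf (7.32 ± 0.267 to 29.8 ± 1.86 FPKM) and Nrg1 (0.71) rose. Axon guidance and adhesion genes gave 12 higher and 4 lower of 26 (median 0.21, camera adjusted p = 0.0838), with Plxnd1 (1.05), Sema3b (0.88) and Efna1 (0.80) higher, while the fall of Efna2 (-0.73) lost its call without control library 1 or IL-22 library 1 (limma adjusted p from 0.00275 to 0.103 over 14 alternatives). Matrix proteases and inhibitors gave 12 higher and 2 lower of 24 (median 0.49, camera adjusted p = 0.003, adjusted p = 0.248 with an estimated correlation). Their median was 0.18 without the filter, 0.27 with a mean FPKM of at least 5 and 0.28 with a pseudocount of 5. Adamts4 (2.08), Mmp10 (1.63) and Mmp9 (1.36) rose. Extracellular matrix genes gave 15 higher and 9 lower of 32, or 16 and 9 adjusted over the list alone (median 0.15, camera adjusted p = 0.0503, adjusted p = 0.422 with an estimated correlation). This list lay near the threshold and passed camera under 7 of 13 alternatives, among them leaving out IL-22 library 1 or IL-22 library 2 (adjusted p from 0.0224 to 0.202 over all 13). The basement membrane gene Nid2 (1.70), Thbs2 (1.25), the collagen cross-linking Lox (1.15) and Fbln1 (1.07) were the largest differences.

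Heat-shock genes were lower as a list, with 3 higher and 10 lower of 17 (median -0.37, camera adjusted p = 0.0312, adjusted p = 0.252 with an estimated correlation). The chaperone genes Hsph1 (-1.78), Dnajb1 (-1.25), Dnaja1 (-1.05) and Hsp90aa1 (-0.98) fell. Oxidative stress genes controlled by NRF2 gave 14 higher and 4 lower of 29 (median 0.18, or 0.11 with a pseudocount of 5 and 0.08 with a mean FPKM of at least 5, camera adjusted p = 0.0409, adjusted p = 0.252 with an estimated correlation). That call was also lost without the filter, with a mean FPKM of at least 5, with quantile normalization, without the trend, and without control library 2 or IL-22 library 1 (camera adjusted p from 0.0232 to 0.0807 over 13 alternatives). The glutathione peroxidase gene Gpx1 fell from 198 ± 2.05 to 27.7 ± 2.03 FPKM (-2.80 ± 0.07, limma adjusted p = 2.74e-08), while the cystine transporter gene Slc7a11 (1.75) and the metallothioneins Mt1a (1.37) and Mt2A (1.28) rose. Cytoplasmic ribosomal protein genes shifted by a small amount, with 38 higher and 0 lower of 76, or 36 and 0 adjusted over the list alone (median 0.19, or 0.035 with quantile normalization, camera adjusted p = 2.8e-06, adjusted p = 0.252 with an estimated correlation), and quantile normalization ended that call (camera adjusted p from 8.02e-09 to 0.197 over 13 alternatives). Rps18 (0.50), Rpl12 (0.48), Rpl17 (0.48) and Rpl24 (0.45) had the largest differences, and all are uncertain to the extent that their processed pseudogenes share reads. Oxidative phosphorylation genes gave 8 higher and 13 lower of 56, or 7 and 13 adjusted over the list alone (median -0.0034, camera adjusted p = 0.681), with Atp5g1 (-0.64), Ndufs3 (-0.61) and Cycs (-0.58) lower and Ndufa1 (0.45) higher. The mitochondrially encoded genes had 0 rows.

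TGF-beta and BMP response genes gave 7 higher and 12 lower of 24 (median -0.21, camera adjusted p = 0.201). Id2, the BMP-induced Id1 (-1.60) and Smad6 (-1.53) and the actin-binding Tagln (24.8 ± 2.16 to 4.41 ± 0.186 FPKM) fell. Wnt and Notch genes gave 4 higher and 7 lower of 17 (median -0.19, camera adjusted p = 0.324). The Notch modifier Lfng (-1.93) and the Notch target Hes1 (-0.70) fell, and the ligand gene Dll1 (1.15) and the Wnt inhibitor gene Wif1 (0.76) rose. Outside the lists, the homeobox gene Dlx2 (-2.13), Dhrs4 (-2.13) and Xkr5 (-2.06) were among the 10 largest falls named by the rule. Fibroblast markers gave 5 higher and 3 lower of 8 (median 0.26, camera adjusted p = 0.443), with Fbln1 and Gsn (0.51) higher, S100a4 lower (-0.56) and the fall of Col1a1 (-0.55) lost without control library 1 (limma adjusted p from 0.000283 to 0.0539 over 15 alternatives). Endothelial and pericyte markers had 4 tested members, 2 higher and 1 lower, or 3 and 1 adjusted over the list alone. Of these Des (0.213 ± 0.0392 to 2.42 ± 0.281 FPKM) and Flt1 (1.07) rose, and Cspg4 (-0.22) lost its call without any 1 of the 4 libraries, without the trend and under both other scalings. Epithelial and perineurial markers gave 3 higher and 1 lower of 5 (median 0.28, camera adjusted p = 0.317). The glucose transporter gene Slc2a1 rose (1.41) and Itga6 fell (-0.52). Tjp1 (0.30) lost its call without the filter, control library 1 or IL-22 library 1, and Cldn4 (0.28) without the filter, with quantile normalization and without any 1 of the 4 libraries.

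Several rows with the largest differences belong to ribosomal RNA or to near-identical copies, which can share reads, and are uncertain. Rn28s was listed at 4015 and 2715 FPKM in controls and at 0 in both IL-22 libraries, and Rn45s at 2872 and 2103 FPKM and at 0. Rn5-8s.6, a copy of the 5.8S RNA, measured 22.5 ± 8.16 and 612 ± 4.37 FPKM. Ybx1, an RNA-binding protein gene, measured 0.763 ± 1.06 and 46.2 ± 9.17 FPKM, beside 1042 ± 50.1 and 943 ± 26.4 FPKM in the row of its copy Ybx1-ps3. Vps37c was listed at 6.62 and 6.12 FPKM in controls and at 0 with IL-22, while a second row of the symbol, Vps37c.1, measured 6.56 ± 0.424 and 15.1 ± 0.345 FPKM. LOC310926.1 likewise was listed at 182 and 152 FPKM and at 0, and LOC310926 measured 142 ± 16.9 and 1144 ± 99.8 FPKM. Ybx1-ps3 and the rows of Vps37c and LOC310926 were named after their values were seen.

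The lncRNA table gave few calls. Of 4454 lncRNA rows tested with limma, 36 were higher and 25 lower with IL-22, and 888 had an unadjusted p under 0.05. NONRATG019112 had the largest rise, listed at 0 and 0.742 FPKM in controls and at 3369 and 2246 FPKM with IL-22 (limma adjusted p = 0.0216), and NONRATG009192 was listed at 0 in both controls and at 400.2 and 200.1 FPKM with IL-22. NONRATT010011 was listed at 800.4 and 934 FPKM in controls and at 0 with IL-22 (limma adjusted p = 0.0126), and NONRATG009505 at 400.2 and 311 FPKM and at 0. At the libraries' relative depth, the values of the higher group stood in the ratio of 3 to 2, 2 to 1, 2 to 3 and 1 to 1 whole reads for these 4 rows in turn, and read counts are not given. Over 11 alternatives NONRATG019112 lost its call under 6 and NONRATG009192 under 5, both without any 1 of the 4 libraries, and NONRATT010011 and NONRATG009505 lost theirs under 4, among them leaving out control library 1 or either IL-22 library (limma adjusted p from 0.00607 to 0.191 over all 4 rows). In all, 46 of the 61 called lncRNAs were listed at 0 in both libraries of a group. The identifiers are not paired with names or positions in the table, and gene-level and transcript-level identifiers stand side by side. The counts were 0 and 0 without control library 1, IL-22 library 1 or IL-22 library 2 (limma, 855, 606 and 650 at an unadjusted p under 0.05), and 25 higher and 111 lower without control library 2.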

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

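Chosen after seeing the data were the alternatives of 1 row per symbol, without rows listed at 0 in both libraries of a group, with a difference of at least 1 log2, with gene-level or transcript-level identifiers alone, and with lncRNAs above 0 in all 4 libraries, and the others before. In the gene table the counts stayed within 1.5 times of 2619 higher and 2918 lower under every other pseudocount, filter, scaling or variance setting tried, and 0 genes were called in opposite directions. Leaving out each library gave 2120 to 2281 higher and 2361 to 2491 lower, of which 2068 to 2146 and 2262 to 2378 were shared with the fit of all libraries. Demanding a difference of at least 1 log2 left 444 higher and 269 lower. The 2-fold separated counts of 444 higher and 269 lower became 204 and 136 with a pseudocount of 5, which shrinks low genes, 1162 and 1110 at 1.5-fold, and 293 higher with a mean FPKM of at least 5, which tests fewer genes. Of the 133 tested genes named by the rule 11 lost their call under at least 1 alternative, as given with their values, and 0 changed sign. Cd14 passed without IL-22 library 2 and with the replicate number as a block (limma adjusted p from 0.00178 to 0.632 over 14 alternatives), and Cd68 with quantile normalization and without trend (0.0153 to 0.391). The median of every list that did not pass camera changed sign or moved by more than 1.5 times under at least 1 alternative. The cause was not tested.

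Of the lists, 13 higher and 3 lower became 0 and 0 with an estimated correlation, a version with 2 residual degrees of freedom. Fry, which does not compare a list with other genes, called 23 higher and 4 lower. Leaving out each library gave 11 to 13 higher and 3 lower. The direction of the camera test on repair Schwann cell genes, which did not pass, was reversed with quantile normalization (median -0.05431, adjusted p = 0.983), without trend (-0.04429) and without control library 1 (-0.07635), and that of oxidative phosphorylation genes without control library 1 (0.001929). Over the left-out libraries their medians ran from -0.1101 to 0.01517 and from -0.06261 to 0.001929, and the cause was not tested. Camera has no robust setting, so that alternative was not run for lists.

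The lncRNA calls depend on single libraries. Leaving out a library gave 0 to 25 higher and 0 to 111 lower, with 0 and 0 without control library 1, IL-22 library 1 or IL-22 library 2 and 25 and 111 without control library 2. Tested apart, gene-level identifiers gave 19 higher and 13 lower and transcript-level ones 17 and 15, as fewer rows were tested. Without the filter 24 were higher and 15 lower. Among the 3832 rows above 0 in all 4 libraries limma called 0 higher and 0 lower (787 at an unadjusted p under 0.05).

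The labels number libraries 1 and 2 in both groups. Deviations of same-numbered libraries from their group means correlated at -0.00197 in the gene table and 0.0788 in the lncRNA table, so the numbers are not taken as pairs. With the replicate number as a block, limma called 2755 genes higher and 3070 lower, 0 lncRNAs higher and 0 lower (666 at an unadjusted p under 0.05), and camera 14 lists higher and 3 lower. The block left 1 residual degree of freedom. Absolute depth is unknown, so no limit from counting is given. Simulated 2-fold changes, in values without whole-read steps, were recovered in 6% of lncRNAs and 100% of genes.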

Other observations

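Apart from the limma fits and the fixed lists, the tests in this part were chosen after the results had been seen. So were its genes outside the naming rule. Symbols were grouped by the letters before their first digit, and 145 such families with at least 8 tested symbols were tested with camera. Of these 17 passed, and 0 passed with an estimated correlation (adjusted p = 0.839 for each family named here). That version again had 2 residual degrees of freedom, so it says little about correlation within a family. Among the splicing factors with the prefix Srsf 9 of 11 were lower and 1 higher (median -1.04, camera adjusted p = 0.00316), with Srsf6 at -1.56 and Srsf7 from 124 ± 11.4 to 45.8 ± 4.43 FPKM. Among the DEAD-box RNA helicases (Ddx) 22 of 32 were lower and 1 higher (median -0.55, camera adjusted p = 0.000371), among them Ddx21, which acts in ribosomal RNA synthesis (-1.35). RNA polymerase subunits (Polr) gave 16 lower and 1 higher of 25 (median -0.36, camera adjusted p = 0.00839), with Polr1a, the catalytic subunit of the polymerase that makes ribosomal RNA, from 23.9 ± 1.05 to 11.8 ± 0.00700 FPKM. Nop56, a nucleolar protein gene, fell from 118 ± 5.39 to 39.6 ± 0.670 FPKM. The direction and the camera call of these families held with quantile normalization (adjusted p = 0.00628 for Srsf, 0.00122 for Ddx and 0.0227 for Polr) and with median-of-ratios size factors.

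Genes of the rat major histocompatibility complex (prefix RT) rose, with 17 higher and 1 lower of 24 (median 0.48, camera adjusted p = 0.00362, adjusted p = 0.839 with an estimated correlation), a call that held under both other scalings (adjusted p = 0.0103 and 0.00417). RT1-A2 measured 21.4 ± 1.52 and 35.0 ± 2.66 FPKM. Some of these genes are near-identical and can share reads, so single rows are uncertain. Rows that share reads would also not be separate genes in the family count or in camera. Immunoproteasome subunits fell at the same time, Psmb8 from 214 ± 24.5 to 107 ± 4.12 FPKM and Psmb9 from 131 ± 6.12 to 99.9 ± 0.815 FPKM, beside Psmb10. Import genes of the mitochondrial inner membrane (Timm) gave 10 lower and 0 higher of 12 (median -0.49, camera adjusted p = 0.0171, and 0.0373 with quantile normalization), and semaphorins (Sema) 7 higher and 0 lower of 11 (median 0.64, camera adjusted p = 0.0376), a call lost with quantile normalization (adjusted p = 0.0769).

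The 16 list calls, among them chemokines, amino-acid response and glycolysis, were weighed against technical sources. None held with an estimated correlation, where 2 residual degrees of freedom left little power. Depth did not part the groups, since relative to control library 1 it was 1.28 in control library 2 and 1.08 in both IL-22 libraries, and its effect on the lists was not tested. Leukocytes carried into the IL-22 dishes would bring their abundant transcripts with Cxcl1, but the median of 20 leukocyte markers with IL-22 was 0.0219 FPKM and Ptprc, Tyrobp and Aif1 were at or near 0. A shortage of glucose in the IL-22 dishes would lower Txnip, which glucose induces, but Txnip rose by 1.46 (limma adjusted p = 6.29e-07), as did Arrdc4 (0.85). Whether another change between the groups raised these genes was not tested, so their rise does not exclude such a shortage. A response to IL-22, later cytokines, a shortage of amino acids or another difference between dishes may each still account for part of these calls. So may a bacterial product carried with the recombinant protein. The endotoxin receptor gene Tlr4 measured 0.608 and 0.643 FPKM and lay under the expression minimum. Its co-receptor gene Ly96 rose from 0.510 ± 0.721 to 4.42 ± 0.00253 FPKM (1.93, limma adjusted p = 0.000382), with the controls at 0 and 1.02 FPKM. The labels give 48 h for IL-22 and no time for the controls, so time in culture without serum may differ between the groups. If so, its effect cannot be told apart from that of IL-22.

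The lncRNA calls may come from the sampling of a few reads. Among 72 group values of the 61 called lncRNAs with both libraries above 0, 62.5% (45) stood in a ratio of 1 to 3 whole reads at the libraries' relative depth, within 0.5%. Ratios shifted at random 1000 times gave 2.3% on average and at most 9.7%, and 6403 gene rows of at least 10 FPKM gave 3.3%. The higher values of NONRATG019112, NONRATG009192, NONRATT010011 and NONRATG009505 all stood in such ratios, though the 0.742 FPKM of NONRATG019112 in a control library is too small for a whole read on that scale. Real differences in the other called lncRNAs stay open.

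Of 28 STAT3 target genes 21 were higher (camera adjusted p = 1.69e-06, adjusted p = 0.24 with an estimated correlation), although Il22ra1 was listed at 0 in all libraries, and Il20ra, the related receptor gene, was also at 0. The list shares Bcl3 with the NF-kappaB list, and shared members were not split out, so its rise need not reflect STAT3 alone. If it does reflect STAT3, a candidate explanation is that a cytokine made by the cells signalled in place of IL-22. What would induce such a cytokine without the IL-22 receptor was not tested. LIF stays open as that signal: Lif rose by 2.54, but its receptor gene Lifr had a highest value of 0.0 FPKM. As for Il22ra1, such a 0 can be a failed estimate or can mean that the gene is not expressed. Of 17778 gene rows 5296 were at 0 in all 4 libraries. If Lifr is not expressed, LIF would lack its receptor. IL-11 had the ligand and receptor transcripts that such a loop would need, though Il11 was low. Il11 rose from 0.446 ± 0.180 to 3.25 ± 0.533 FPKM (1.56, limma adjusted p = 8.86e-05). Its receptor gene Il11ra1 fell from 38.7 ± 4.12 to 31.7 ± 2.07 FPKM (-0.28, limma adjusted p = 0.0257), and Il6st measured 27.7 ± 0.758 and 28.1 ± 0.806 FPKM. Whether IL-11 drives the targets was not measured, and other cytokine genes that rose, such as Il10, were not weighed. An Il22ra1 level below what these libraries detect, or a failed estimate of its row, stays open.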
